A study of Mus musculus with 6 samples.

How the data were processed

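The libraries were made from total RNA of frozen mouse liver, in 3 samples given ANIT and 3 given ANIT plus celastrol, and groups and replicate numbers were taken from the library titles. The deposited values are FPKM (fragments per kilobase of gene, scaled to the number of fragments of the library), 1 table per library with gene symbols, per the file headers. Reads were aligned to the mouse build mm10 and counted with HISAT2 and featureCounts, per the submitters' processing notes, which give no versions. How counts became FPKM, the gene annotation, the gene lengths and the strand setting are not given in the sources used here, so antisense and overlapping genes, and near-identical paralogs such as the Saa, Mup, Orm, Gsta, Gstm, Cyp2c, Cyp2d, Cyp3a, Serpina and Sult2a genes, are uncertain. The smallest FPKM listed was 0.01 and no zero was listed, and a symbol not listed in a library was set to 0. Symbols numbered 18253 in at least 1 library. From 23 to 24 rows per library carried names turned into dates, and 2 such names that occurred more than once were left out. No mitochondrially encoded gene was listed, so their share could not be used as a check of RNA quality. Of the symbols, 17576 (96.3%) matched a gene of GENCODE release M21, which uses the same build, and coordinates and exon lengths came from it.

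An FPKM table gives no read totals. Depth was therefore estimated from the steps between low values (0.1 to 1 FPKM) of genes with 1 transcript and 400 to 2500 bases, where 1 read is worth a fixed amount, and the means were 19340000 ± 458258 reads for ANIT and 19620000 ± 208806 reads for celastrol (SD, n = 3 each). The gene lengths behind the values are unknown, so no counts were rebuilt and no count model was run. At this depth 1 FPKM over 1 kilobase is 18.9 to 19.8 reads, and genes well below 1 FPKM rest on few reads. The sum of FPKM was 540054 ± 6809 for ANIT and 589793 ± 9923 for celastrol (SD, n = 3 each, exact permutation p = 0.1, the smallest possible). The 10 most abundant genes took 21.3 ± 0.896% of the FPKM sum with ANIT, and 33.2%, 20.7% and 31.5% in celastrol replicates 1, 2 and 3.

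The design written before the data were examined assumed counts and named a fallback for normalized values, which was used. Genes with at least 1 FPKM in at least 3 libraries were tested on log2(FPKM + 1) with limma 3.58.1 in R 4.3.3, with an empirical Bayes trend, robust variance and the group as the only term, and Benjamini-Hochberg adjusted p under 0.05. Log2 fold changes are on the log2(FPKM + 1) scale and understate the change of genes near or below 1 FPKM. Group means ± SD are of FPKM. Before the data were examined 37 gene lists (12 of a main tier and 25 of a second tier) were written from textbook knowledge. Lists with at least 5 tested members were tested with camera (preset inter-gene correlation 0.01), which compares a list with all other genes, and each list's call was repeated with an estimated correlation and with fry. The estimate rests on few libraries, so a list that failed with it was not thereby shown to be unchanged. Lists for lymphocytes, pancreatic acinar cells and mitochondrially encoded genes had too few tested members.

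Named genes followed a rule fixed at the same time. It takes the 6 highest and 6 lowest log2 fold changes among genes past the threshold whose groups do not overlap and whose average log2 is at least 1 (planned on log2 CPM, applied here to log2(FPKM + 1)), leaving out unnamed gene models. It adds the 2 members with the smallest p of each main-tier list and of each second-tier list that passed, and Nr1h4, Nr0b2, Sirt1, Cyp7a1, Cyp8b1, Abcb11, Slc10a1, Abcc4, Tnf and Il6 whatever their values. Other members named beside small counts, and all genes named only in the closing section, were chosen after their values were seen. Of the genes the rule names, 1 is not reported here. Genes of the rule below the filter have p-values from the fit without it. Groups did not overlap for 4761 (44.9%) of the tested genes, where chance gives 10%.

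The fit was tested on simulated data drawn from the means and residual SDs of the real genes, in 5 simulations of this comparison over a mean of 10436 tested genes with 200 changed. It recovered 75.6% of genes changed 2-fold and 92.2% of those changed 4-fold, and 5.62% of calls were false. The changed list was found in all 5 simulations, and 0 of 200 unchanged lists were called. Simulated genes varied independently, and as many were set to rise as to fall. Members of real lists varied together (estimated correlation of 0.24 for Nrf2 targets and 0.61 for cholesterol synthesis, for example), and most real calls were lower. These rates therefore do not carry over to such lists or to a shift of most genes. Other settings chosen before the data were examined were a pseudocount of 0.1, no filter, non-robust variance, the replicate number as a block, a test against a fold of 1.5, the 20 most abundant genes left out with rescaling by the remaining reads, and each library left out in turn. Median-ratio scaling, quantile normalization, rescaling to TPM and a mean of at least 5 FPKM were added after the data were seen. Prior to any of these the tables were read with Python 3.11.15, pandas 2.3.3 and numpy 2.4.6, exact permutation tests used scipy 1.17.1, and plots were drawn with matplotlib 3.10.9.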

Results

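RNA sequencing profiles were obtained from the livers of C57BL/6 mice labelled as postnatal day 21, given alpha-naphthylisothiocyanate (ANIT), a chemical that injures bile duct cells and is used to induce cholestasis in rodents. In 3 libraries the animals had received ANIT, and in 3 they had also received celastrol, a plant triterpenoid with anti-inflammatory activity. All 6 libraries are labelled with 5 days of treatment. None of the 6 libraries came from untreated mice, so the values show how the celastrol group differed from the ANIT group and not how either differed from normal liver. The labels do not say that each library came from a separate animal, and the p-values measure the spread between these samples. Between 15898 and 16402 gene symbols were listed per library, and 14417 were listed in all 6. The depth, estimated from the spacing of the lowest values, was 18940000, 19240000 and 19840000 reads for ANIT replicates 1, 2 and 3 and 19720000, 19380000 and 19760000 reads for celastrol replicates 1, 2 and 3 (exact permutation p = 0.4, two-sided). The smallest two-sided p that 3 against 3 libraries allow in such a test is 0.1.

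The comparison asks which liver transcripts celastrol changes during ANIT-induced cholestasis. Genes of the Nrf2-controlled oxidative stress response (20 of 24 tested), cholesterol synthesis (22 of 25) and the immediate early response (11 of 15) were lower in the celastrol group, as were 8 of 19 bile transporters and 11 of 19 inflammatory genes and NF-kB targets. Genes of acute phase plasma proteins (14 of 28) and pericentral hepatocytes (8 of 15) were higher, as was the bile acid receptor FXR. The largest fall among named genes on the log2(FPKM + 1) scale was that of Gstm3, a glutathione S-transferase, from 1521 ± 269 to 8.55 ± 5.72 FPKM (SD, n = 3 each), a log2 fold change of -7.47 (SE 0.40, limma adjusted p = 0.00024). By the ratio of group means Gsta1, below 1 FPKM with celastrol, fell further (456-fold against 178-fold for Gstm3). The largest rise among named genes on the log2(FPKM + 1) scale was that of Cyp8b1, the sterol 12-alpha-hydroxylase that directs bile acid synthesis toward cholic acid, from 0.157 ± 0.0643 to 19.9 ± 5.85 FPKM (SD, n = 3 each), a log2 fold change of 4.13 (SE 0.20, limma adjusted p = 0.00011). Of 10593 genes tested by limma on log2(FPKM + 1), 2652 passed an adjusted p of 0.05, with 467 higher and 2185 lower in the celastrol group. Counts of rises and falls within a list are to be read against these shares. The median log2 fold change of all tested genes was -0.17, and median-ratio scaling moved it to -0.02 and the split to 793 higher and 1170 lower genes. The split was 729 to 1172 with the 20 most abundant genes left out and 873 to 952 after quantile normalization. Rescaling to TPM moved the median to -0.30. The count of 2652 was 1485, 1166 and 1744 without ANIT replicates 1, 2 and 3, and 1117, 3810 and 1677 without celastrol replicates 1, 2 and 3.

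**Figure D1:**
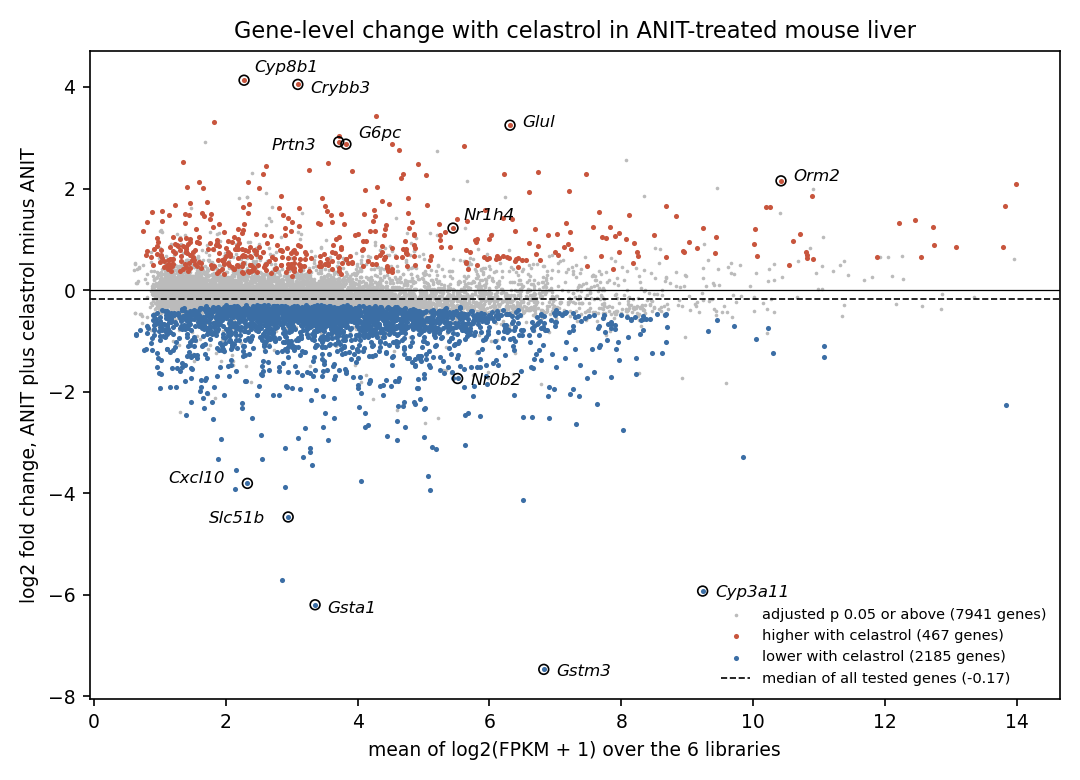
Each point is 1 of the 10593 tested genes, with the mean of log2(FPKM + 1) over the 6 libraries on the horizontal axis and the log2 fold change of ANIT plus celastrol minus ANIT on the vertical axis. The 467 genes higher with celastrol are red, the 2185 lower genes are blue, and the dashed line marks the median of all tested genes at -0.17. Gstm3, at -7.47, and Cyp8b1, at 4.13, lie at the ends of the vertical range.

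Among genes of bile acid synthesis, 5 of 18 tested members rose and 5 fell, or 7 and 5 when adjusted over the list alone. Under median-ratio scaling 7 rose and 3 fell, and after quantile normalization 8 rose and 2 fell. The list lay above other genes (camera adjusted p = 0.00046, adjusted p = 0.50 with an estimated correlation). Its median log2 fold change was 0.51, and 0.23 without celastrol replicate 2. Besides Cyp8b1, Cyp2c70, the mouse enzyme that makes muricholic acids, rose from 236 ± 65.3 to 744 ± 186 FPKM (SD, n = 3 each), with a log2 fold change of 1.66 (SE 0.25, limma adjusted p = 0.0044). Cyp7a1, the rate-limiting enzyme of the classic pathway, lay below the abundance filter. Its FPKM was 0.03, 0.01 and 0.01 in the ANIT libraries and 0.58, 7.92 and 1.0 in the celastrol libraries. Without the filter it did not pass (limma adjusted p = 0.18), and it passed with a pseudocount of 0.1 (adjusted p = 0.038) or without celastrol replicate 2 (adjusted p = 0.0089). The 3 further members that rose were Slc27a5, Cyp7b1 and Acnat1, and those that fell were Acox2, Baat, Akr1d1, Amacr and Cyp39a1. Of these 8 calls, all but that of Slc27a5 were lost when at least 1 of the libraries was left out (adjusted p from 0.051 to 0.12). Those of Amacr and Cyp39a1 were also lost under median-ratio scaling (adjusted p of 0.061 and 0.082).

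Nr1h4, which encodes the bile acid receptor FXR (chromosome 10, positions 89454234 to 89533585 in mm10), rose from 27.6 ± 1.65 to 65.7 ± 3.52 FPKM (SD, n = 3 each), a log2 fold change of 1.22 (SE 0.11, limma adjusted p = 0.00083). Nr0b2, which encodes the FXR-induced repressor SHP (chromosome 4, positions 133553376 to 133556536), fell from 83.6 ± 14.9 to 24.1 ± 2.39 FPKM (SD, n = 3 each), a log2 fold change of -1.74 (SE 0.16, limma adjusted p = 0.00085). Sirt1, a deacetylase that acts on FXR, measured 3.02 ± 0.315 and 3.64 ± 0.603 FPKM (SD, n = 3 each) and did not pass (log2 fold change 0.20, SE 0.12, limma adjusted p = 0.26). Of the 23 tested receptors and sirtuins, 1 rose and 4 fell, with the same counts when adjusted over the list alone, and the list did not pass (camera adjusted p = 0.42). The other members that fell were Nr1i2, Rora and Sirt5. The Rora call was lost after quantile normalization and without ANIT replicate 2 or celastrol replicate 1 (adjusted p from 0.061 to 0.067). The Sirt5 call was lost under median-ratio scaling (adjusted p = 0.12), with the 20 most abundant genes left out, after quantile normalization, without the filter, and without ANIT replicate 1 or 2 or celastrol replicate 1 or 3 (adjusted p from 0.067 to 0.15). Under median-ratio scaling 2 members rose and 3 fell, and after quantile normalization 2 rose and 2 fell.

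None of the 19 tested transporters of bile acids and bile rose, and 8 fell, or 10 when adjusted over the list alone. The list did not pass against other genes (camera adjusted p = 0.10). It passed under median-ratio scaling (adjusted p = 0.018), without celastrol replicate 2 (adjusted p = 0.016) and by fry (fry adjusted p = 0.041). Slc51b, the beta subunit of the basolateral bile acid exporter (chromosome 9, positions 65412714 to 65422955), fell from 35.9 ± 9.03 to 0.713 ± 0.615 FPKM (SD, n = 3 each), a log2 fold change of -4.47 (SE 0.29, limma adjusted p = 0.00049). The alpha subunit, Slc51a, was not listed under that symbol in any library, so its change is unknown. Abcb1a, a multidrug efflux pump, fell from 14.3 ± 2.19 to 0.31 ± 0.19 FPKM (SD, n = 3 each), with a log2 fold change of -3.54 (SE 0.15, limma adjusted p = 3.4e-05). Abcb11, the bile salt export pump of the canalicular membrane, fell from 281 ± 72.0 to 105.2 ± 48.4 FPKM (SD, n = 3 each), a log2 fold change of -1.47 (SE 0.32, limma adjusted p = 0.018). That call was lost without ANIT replicate 1 or 2 or celastrol replicate 1 or 3 (adjusted p of 0.051, 0.065, 0.067 and 0.056). Slc10a1, the uptake transporter NTCP, measured 200.6 ± 42.2 and 206.9 ± 43.7 FPKM (SD, n = 3 each) and did not pass (limma adjusted p = 0.89). The exporter Abcc4 lay below the filter, at 0.44, 0.77 and 0.99 FPKM with ANIT and 0.25, 0.29 and 0.25 FPKM with celastrol (limma adjusted p = 0.070 without the filter). It passed when rescaled to TPM (adjusted p = 0.038) or without ANIT replicate 1 (adjusted p = 0.032).

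**Figure D2:**
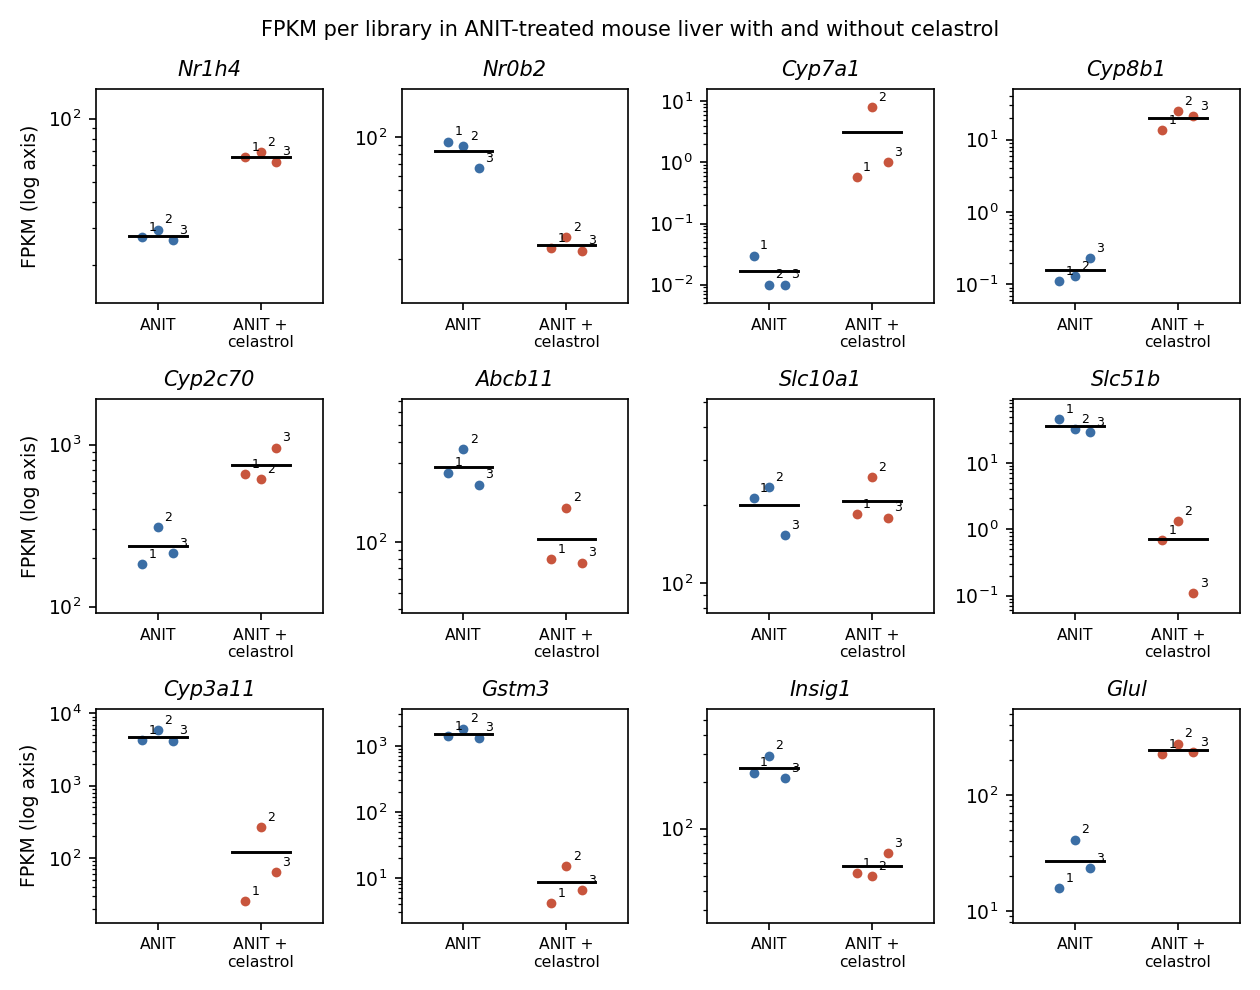
FPKM in each library, on a log axis with its own range in each panel, for 12 genes in the ANIT group (blue) and the ANIT plus celastrol group (red). Points are libraries numbered by replicate and horizontal lines are group means. In 11 panels the 3 libraries of one group lie apart from those of the other, and for Slc10a1 they overlap.

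Genes of the oxidative stress response controlled by Nrf2 fell together. Of 24 tested members 20 fell and none rose, or 21 fell when adjusted over the list alone, with a median log2 fold change of -1.58 (camera adjusted p = 3.0e-09, adjusted p = 0.44 with an estimated correlation). Srxn1, which restores oxidised peroxiredoxins, fell from 67.3 ± 14.4 to 7.81 ± 1.21 FPKM (SD, n = 3 each), a log2 fold change of -2.94 (SE 0.18, limma adjusted p = 0.00020). Gsta4 fell from 135.9 ± 29.1 to 9.62 ± 8.32 FPKM (SD, n = 3 each), with a log2 fold change of -3.94 (SE 0.53, limma adjusted p = 0.0057). Gsta1 measured 47.42, 101.29 and 134.15 FPKM with ANIT, was not listed in celastrol replicate 1 and measured 0.43 and 0.19 FPKM in celastrol replicates 2 and 3 (log2 fold change -6.20, limma adjusted p = 0.00051). Gsta and Gstm genes have near-identical copies, so the share of reads given to each member is uncertain. Of 23 tested heat shock genes 5 fell and none rose, or 8 and 1 when adjusted over the list alone, and the list did not pass (camera adjusted p = 0.23). When rescaled to TPM 11 fell and none rose, whereas under median-ratio scaling or quantile normalization 2 fell and 1 rose. Hspa4l had a log2 fold change of -0.83 (limma adjusted p = 0.0041) and Hsp90ab1, a cytosolic chaperone, of -0.77 (limma adjusted p = 0.0087).

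Cytochromes P450 of drug metabolism moved in both directions, with 4 of 29 tested members higher and 9 lower, or 4 and 11 when adjusted over the list alone, and the list did not pass (camera adjusted p = 0.25). Cyp3a11, the main inducible hepatic enzyme of its subfamily, measured 4751 ± 904 FPKM with ANIT and 25.45, 269.3 and 63.66 FPKM in the celastrol libraries (log2 fold change -5.93, SE 0.83, limma adjusted p = 0.0069). Its relative Cyp3a59 fell from 62.2 ± 21.3 to 3.68 ± 1.56 FPKM (SD, n = 3 each), a log2 fold change of -3.75 (SE 0.30, limma adjusted p = 0.00086). Cyp2a5 measured 393 ± 137 FPKM (SD, n = 3) with ANIT and 8.86, 88.46 and 10.53 FPKM with celastrol. Its log2 fold change was -4.13 (SE 0.89, limma adjusted p = 0.024), and the call was lost without any 1 ANIT library, celastrol replicate 1 or celastrol replicate 3 (adjusted p from 0.067 to 0.088). Cyp2d9 rose from 151 ± 3.99 to 310.0 ± 13.9 FPKM (SD, n = 3 each), a log2 fold change of 1.03 (SE 0.12, limma adjusted p = 0.0018). These families also hold close paralogs whose reads may not be separable.

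Cholesterol synthesis genes fell in 22 of 25 cases and rose in none, or 23 fell when adjusted over the list alone. Their median log2 fold change was -1.66 (camera adjusted p = 8.8e-09, adjusted p = 0.50 with an estimated correlation). Insig1, an SREBP-regulated protein of the endoplasmic reticulum, fell from 245 ± 43.3 to 57.3 ± 11 FPKM (SD, n = 3 each), a log2 fold change of -2.08 (SE 0.19, limma adjusted p = 0.00082). Lipogenesis genes fell in 11 of 21 cases and rose in none, or 13 fell when adjusted over the list alone (camera adjusted p = 0.010, adjusted p = 0.75 with an estimated correlation). The lipogenesis call was lost without ANIT replicate 2 (adjusted p = 0.062) and with only genes at a mean of 5 FPKM or more (adjusted p = 0.11). Acly, which makes cytosolic acetyl-CoA, fell from 78.5 ± 0.188 to 23.4 ± 5.07 FPKM (SD, n = 3 each), a log2 fold change of -1.72 (limma adjusted p = 0.00083). Pnpla3 had a log2 fold change of -1.65 (limma adjusted p = 0.0017). Among 34 PPAR-alpha targets and fatty acid oxidation genes 2 rose and 9 fell, with the same counts when adjusted over the list alone, and the list did not pass (camera adjusted p = 0.25). Fgf21, a hormone secreted by hepatocytes, fell from 11.7 ± 5.72 to 0.167 ± 0.0551 FPKM (SD, n = 3 each), a log2 fold change of -3.32 (limma adjusted p = 0.0024). Acot4 had one of -1.90 (limma adjusted p = 0.0012). Genes of gluconeogenesis, the urea cycle and amino acid catabolism lay above other genes (camera adjusted p = 0.0067, adjusted p = 0.75 with an estimated correlation). Of 29 tested members 3 rose and 3 fell, with the same counts when adjusted over the list alone, and under median-ratio scaling 6 rose and 3 fell. The median of 0.07 became -0.06 when rescaled to TPM and lay between -0.08 and 0.13 when 1 library was left out, below 0 without ANIT replicate 2 or 3 or celastrol replicate 2 or 3. This call was lost without ANIT replicate 2 (adjusted p = 0.062), without celastrol replicate 3 (adjusted p = 0.084), without the filter (adjusted p = 0.057) and after quantile normalization (adjusted p = 0.16). G6pc, which releases free glucose, rose from 4.35 ± 1.41 to 41.3 ± 24.1 FPKM (SD, n = 3 each), a log2 fold change of 2.87 (limma adjusted p = 0.0062). Fbp1 rose by a log2 fold change of 1.24 (limma adjusted p = 0.0075). The other members that rose or fell were Hpd, higher, and Gpt, Ass1 and Slc25a13, lower. The 3 falls were lost without celastrol replicate 1 (adjusted p of 0.050, 0.057 and 0.10). That of Slc25a13 was also lost without any 1 ANIT library, celastrol replicate 3 or the filter, and after quantile normalization (adjusted p from 0.050 to 0.087).

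Acute phase protein genes rose in 14 of 28 cases and fell in none, or 18 rose when adjusted over the list alone, with a median log2 fold change of 0.92 (camera adjusted p = 1.19e-15, adjusted p = 0.44 with an estimated correlation). After quantile normalization 6 of the 28 rose. Orm2 rose from 653 ± 58.7 to 2936 ± 596 FPKM (SD, n = 3 each), a log2 fold change of 2.15 (SE 0.19, limma adjusted p = 0.00079), and Orm3 had a log2 fold change of 2.28 (SE 0.28, limma adjusted p = 0.0026). Both encode alpha-1-acid glycoproteins, which are close paralogs. The 10 most abundant genes of each library, which included Saa1 in each, took 33.2%, 20.7% and 31.5% of the FPKM sum in celastrol replicates 1, 2 and 3 and 21.3 ± 0.896% (SD, n = 3) with ANIT. Coagulation and complement genes rose in 11 of 29 cases and fell in 1, with the same counts when adjusted over the list alone (camera adjusted p = 1.6e-08, adjusted p = 0.44 with an estimated correlation). C9, a component of the membrane attack complex, rose from 49.6 ± 14.7 to 190.6 ± 36.2 FPKM (SD, n = 3 each), a log2 fold change of 1.94 (limma adjusted p = 0.0018). Mbl1, a mannose-binding lectin, rose by a log2 fold change of 1.31 (limma adjusted p = 0.0016). The member that fell was Serpind1. Its call was lost under median-ratio scaling (adjusted p = 0.060), with the 20 most abundant genes left out, without the filter, and without any 1 ANIT library or celastrol replicate 1 or 3 (adjusted p from 0.060 to 0.14). Under median-ratio scaling 15 members rose and none fell, and when rescaled to TPM 9 rose and 2 fell.

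Inflammatory cytokines and NF-kB targets fell in 11 of 19 tested cases and rose in none, with the same counts when adjusted over the list alone. The list had a median log2 fold change of -0.61 and did not pass (camera adjusted p = 0.086). It passed under median-ratio scaling (adjusted p = 0.0079) and by fry (fry adjusted p = 0.041). Cxcl10, a chemokine, fell from 19.4 ± 10.9 to 0.35 ± 0.187 FPKM (SD, n = 3 each), a log2 fold change of -3.80 (SE 0.34, limma adjusted p = 0.0014). Tnfaip3, a feedback inhibitor of NF-kB, fell from 5.77 ± 1.83 to 0.643 ± 0.251 FPKM (SD, n = 3 each), a log2 fold change of -2.02 (SE 0.20, limma adjusted p = 0.0011). Tnf measured at most 0.23 FPKM and Il6 at most 0.10 FPKM in any library, below the filter, and neither differed detectably (limma adjusted p of 0.40 and 0.68 without the filter). Immediate early genes fell in 11 of 15 cases and rose in none, or 12 fell when adjusted over the list alone, with a median log2 fold change of -1.13 (camera adjusted p = 6.2e-05, adjusted p = 0.44 with an estimated correlation). Jun, a subunit of AP-1, fell from 13.8 ± 1.63 to 3.82 ± 0.247 FPKM (SD, n = 3 each), a log2 fold change of -1.62 (limma adjusted p = 0.00024). Klf6 had one of -1.80 (limma adjusted p = 0.00037).

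Interferon-stimulated genes rose in 12 of 30 cases and fell in 2, or 16 and 4 when adjusted over the list alone, with a median log2 fold change of 0.36 (camera adjusted p = 8.8e-09, adjusted p = 0.47 with an estimated correlation). Oasl2 rose from 0.60 ± 0.122 to 2.32 ± 0.358 FPKM (SD, n = 3 each), a log2 fold change of 1.05 (limma adjusted p = 0.0019), and Oas2 had one of 0.89 (limma adjusted p = 0.0055). The 2 that fell were Ifih1 and Ddx58, which encode RNA helicases. The Ddx58 call was lost under median-ratio scaling (adjusted p = 0.075), with the 20 most abundant genes left out, after quantile normalization and without ANIT replicate 2 (adjusted p from 0.052 to 0.10). When rescaled to TPM 4 members fell. Neutrophil markers rose in 6 of 15 cases and fell in none, or 7 rose when adjusted over the list alone (camera adjusted p = 8.2e-08, adjusted p = 0.44 with an estimated correlation). Prtn3, a granule protease, rose from 3.82 ± 0.917 to 35.4 ± 6.70 FPKM (SD, n = 3 each), a log2 fold change of 2.92 (limma adjusted p = 0.00020), and Ngp, another granule protein, from 0.193 ± 0.186 to 2.68 ± 1.5 FPKM (limma adjusted p = 0.0091). Macrophage and monocyte markers rose in 4 of 20 cases and fell in 1, or 6 and 1 when adjusted over the list alone (camera adjusted p = 3.7e-07, adjusted p = 0.50 with an estimated correlation). The fall was that of Trem2, and its call was lost under median-ratio scaling (adjusted p = 0.082), with the 20 most abundant genes left out, after quantile normalization, without the filter, and without ANIT replicate 2 or 3 or celastrol replicate 1 or 3 (adjusted p from 0.061 to 0.12). After quantile normalization 8 rose and none fell. Fcgr1, an Fc receptor, had a log2 fold change of 1.01 (limma adjusted p = 0.0062), and Ly6c2 one of 0.62 (limma adjusted p = 0.022), which was lost without ANIT replicate 2 or 3 or celastrol replicate 3 (adjusted p of 0.080, 0.064 and 0.059). Of 16 endothelial markers 1 rose and none fell, with the same counts when adjusted over the list alone (camera adjusted p = 2.3e-05, adjusted p = 0.64 with an estimated correlation). That gene was Stab2, a scavenger receptor of sinusoidal endothelium, with a log2 fold change of 0.65 (limma adjusted p = 0.019), lost without celastrol replicate 1 (adjusted p = 0.056). After quantile normalization 4 rose. Dnase1l3 had a log2 fold change of 0.94 and did not pass (limma adjusted p = 0.063). It passed under median-ratio scaling (adjusted p = 0.033), with the 20 most abundant genes left out (adjusted p = 0.039), after quantile normalization (adjusted p = 0.041) and without celastrol replicate 3 (adjusted p = 0.0097).

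Markers of bile duct cells, the target of ANIT, were scarce. Only 6 of the 22 cholangiocyte and ductular reaction markers reached the filter, of which 2 fell and none rose, with the same counts when adjusted over the list alone, and the list did not pass (camera adjusted p = 0.67). Krt19, a keratin of bile duct cells, measured 1.46 ± 0.0764 and 0.447 ± 0.309 FPKM (SD, n = 3 each) with a log2 fold change of -0.79 (limma adjusted p = 0.014), which was lost without celastrol replicate 1 (adjusted p = 0.054). Cd24a had a log2 fold change of -0.82 (limma adjusted p = 0.012). Among 15 tested stellate cell and matrix genes 1 fell and none rose, with the same counts when adjusted over the list alone, and the list did not pass (camera adjusted p = 0.12). It passed, above other genes, when rescaled to TPM (adjusted p = 0.047), without ANIT replicate 3 (adjusted p = 0.038) and without celastrol replicate 3 (adjusted p = 0.0014). The fall was that of Timp1, a metalloproteinase inhibitor, with a log2 fold change of -1.24 (limma adjusted p = 0.016), lost without celastrol replicate 1 or 3 (adjusted p of 0.064 and 0.053). Fn1, which encodes fibronectin, measured 275 ± 22.6 and 508 ± 170 FPKM (SD, n = 3 each) and did not pass (limma adjusted p = 0.051), but did without celastrol replicate 2 (adjusted p = 0.0027) and among genes at a mean of 5 FPKM or more (adjusted p = 0.040).

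Pericentral hepatocyte genes rose in 8 of 15 cases and fell in none, or 9 rose when adjusted over the list alone, with a median log2 fold change of 1.03 (camera adjusted p = 1.1e-10, adjusted p = 0.44 with an estimated correlation). Glul, the glutamine synthetase of the hepatocytes around the central vein (chromosome 1, positions 153899944 to 153909723), rose from 26.7 ± 13 to 245 ± 28.7 FPKM (SD, n = 3 each), a log2 fold change of 3.25 (SE 0.32, limma adjusted p = 0.0012). Slc1a2, a glutamate transporter, had a log2 fold change of 1.61 (limma adjusted p = 0.0012). Of 18 periportal genes 1 rose and 3 fell, or 1 and 6 when adjusted over the list alone, and the list did not pass (camera adjusted p = 0.68). When rescaled to TPM 1 rose and 6 fell. Male-biased liver genes rose in 6 of 18 cases and fell in 2, or 7 and 3 when adjusted over the list alone (camera adjusted p = 7.6e-06, adjusted p = 0.47 with an estimated correlation). Their median log2 fold change was 0.95, and 0.23 without celastrol replicate 2. The mean log2(FPKM + 1) over the list was 4.81, 5.11 and 5.56 in ANIT replicates 1, 2 and 3 and 5.61, 6.57 and 5.46 in celastrol replicates 1, 2 and 3. The sample details used here give no sex, so a difference in sex between libraries was not examined and cannot be told apart from treatment. The list shares 7 members with other lists, among them C8b, a complement component with a log2 fold change of 1.11 (limma adjusted p = 0.0021). Cytoplasmic ribosomal protein genes fell in 9 of 40 cases and rose in none, or fell in none when adjusted over the list alone (camera adjusted p = 0.0020, adjusted p = 0.85 with an estimated correlation). Those 9 of 40 are close to the share over all tested genes, of which 2185 of 10593 fell. The median log2 fold change of the ribosomal genes was -0.42, or -0.24 after median-ratio scaling and -0.18 after quantile normalization. The number that fell was 32 when rescaled to TPM, 6 after quantile normalization, 2 under median-ratio scaling and 0 with the 20 most abundant genes left out. Rpsa and Rplp0 had log2 fold changes of -0.57 and -0.50 (limma adjusted p of 0.031 and 0.035), which were lost without any 1 ANIT library, without celastrol replicate 1 or 3 (adjusted p from 0.075 to 0.12), without the filter, or with the 20 most abundant genes left out. The Rplp0 call was also lost under median-ratio scaling (adjusted p = 0.076) and the Rpsa call after quantile normalization (adjusted p = 0.081).

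Other genes among the 6 with the largest rise were Crybb3, Csrp3 and Sult2a8. Crybb3, a lens crystallin gene, measured 1.31, 1.22 and 0.79 FPKM with ANIT and 67.11, 17.49 and 32.15 FPKM with celastrol (log2 fold change 4.05, SE 0.46, limma adjusted p = 0.0036). Csrp3, a muscle LIM protein gene, rose from 3.72 ± 1.52 to 36.7 ± 1.83 FPKM (SD, n = 3 each), a log2 fold change of 3.04 (SE 0.21, limma adjusted p = 0.00028). Sult2a8, a hepatic sulfotransferase for bile acids, measured 37.72, 187.0 and 34.42 FPKM with celastrol against 5.25 ± 2.74 FPKM (SD, n = 3) with ANIT (log2 fold change 3.43, SE 0.72, limma adjusted p = 0.022), and the call was lost without any 1 ANIT library (adjusted p from 0.057 to 0.096). In all, 15 of the 34 lists with at least 5 tested members passed, 10 above and 5 below other genes, and no list passed with an estimated correlation. By fry, a test of the list's own direction, 14 lists passed, of which 8 were among those 15. The rest were bile transporters, inflammatory genes, cholangiocyte, adipocyte and female-biased genes (fry adjusted p = 0.041 each) and p53 targets (fry adjusted p = 0.0025). Bile acid synthesis, gluconeogenesis and interferon-stimulated genes passed camera but not fry (fry adjusted p of 0.10, 0.72 and 0.10). So did macrophage, endothelial, male-biased and ribosomal genes (fry adjusted p of 0.23, 0.41, 0.16 and 0.076). The lists not described above did not pass (camera adjusted p of 0.42 for the unfolded protein response, 0.12 for p53 targets, 0.35 for the cell cycle, 0.82 for glucuronidation and sulfation, 0.84 for erythroid, 0.15 for adipocyte, 0.55 for female-biased, 0.68 for fetal, 0.71 for circadian clock and 0.72 for respiratory chain genes). Of those, p53 targets fell in 7 of 15 cases and rose in none, with the same counts when adjusted over the list alone (4 and 1 after quantile normalization). Adipocyte markers fell in 3 of 6 cases and rose in none, or 4 fell when adjusted over the list alone. Without the filter 7 of the lists that did not pass did so, those of bile transporters, inflammatory genes, cholangiocyte markers, heat shock, PPAR-alpha targets, p53 targets and the cell cycle (adjusted p from 0.00016 to 0.016). Adipocyte markers passed under median-ratio scaling (adjusted p = 0.033) and without celastrol replicate 2 (adjusted p = 0.022), respiratory chain genes without celastrol replicate 2 (adjusted p = 0.00099) and p53 targets without celastrol replicate 3 (adjusted p = 0.033). Cytochromes P450 passed among genes at a mean of 5 FPKM or more (adjusted p = 0.015). For receptors and sirtuins, cytochromes P450, glucuronidation and sulfation, fetal genes and clock genes the test put the list above other genes while its median was below 0. For stellate and cell cycle genes the median was above 0 and the mean below 0. Median-ratio scaling turned the medians of receptors and sirtuins and of cytochromes P450 above 0, and rescaling to TPM turned those of stellate and cell cycle genes below 0.

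**Figure D3:**
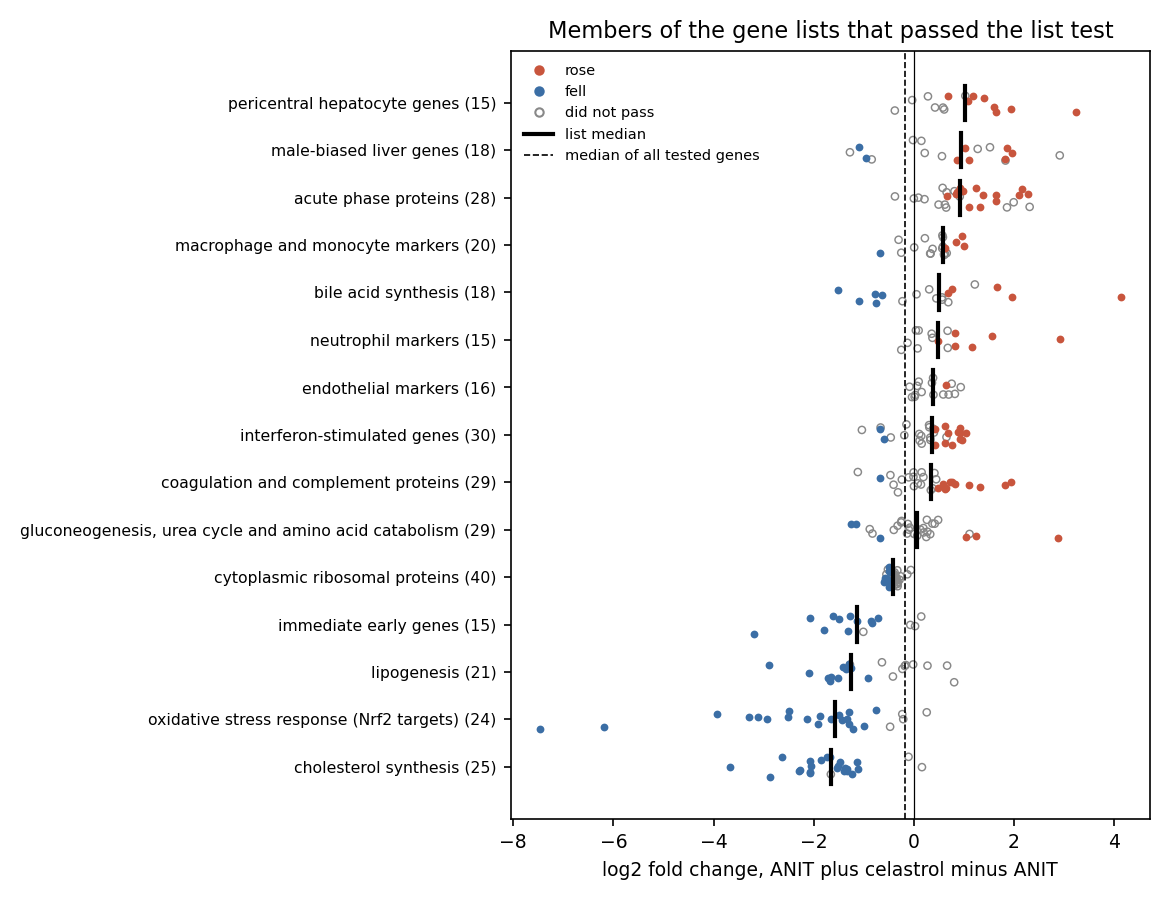
Log2 fold change (ANIT plus celastrol minus ANIT) of every tested member of the 15 lists that passed the list test, with the number of tested members after each name. Filled points passed an adjusted p of 0.05 (red higher, blue lower), open points did not, thick bars are list medians, and the dashed line is the median of all tested genes at -0.17. Medians run from -1.66 for cholesterol synthesis to 1.03 for pericentral genes, and the median of the gluconeogenesis list, 0.07, turns to -0.06 when values are rescaled to TPM and lies between -0.08 and 0.13 when 1 library is left out.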

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

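Median-ratio scaling, quantile normalization, rescaling to TPM and the mean of 5 FPKM were chosen after seeing the data. Testing against a fold of at least 1.5 left 209 genes (47 higher, 162 lower) of 2652, as its construction demands, and ended the call of 20 named genes. Scaling moved the balance of directions. Higher and lower genes numbered 793 and 1170 under median-ratio scaling, 729 and 1172 with the 20 most abundant genes left out, and 873 and 952 after quantile normalization, and rescaling to TPM called 4202 genes with 3813 lower. No gene called in both the original and another setting changed sign. Leaving out 1 library gave 1117 to 3810 genes in all (196 to 476 higher, 911 to 3334 lower), where fewer samples lower the power. The highest came without celastrol replicate 2 and the cause was not tested. Leaving out 1 library gave 13 to 18 passing lists against 15, no filter gave 23 (2 more lists tested, and lower genes), and an estimated correlation gave 0, with 2 lists at an unadjusted p under 0.05, against 14 by fry. Over all alternatives no named gene past the threshold changed sign and no passing list changed sides against other genes. The median of the gluconeogenesis, urea cycle and amino acid list did change sign, from 0.07 to -0.06 when rescaled to TPM and to between -0.08 and 0.13 with 1 library left out. Named genes kept their side of the threshold in 814 comparisons, lost it in 57 and gained it in 11, and lists did so in 507, 28 and 31. The replicate block, a paired fit by replicate number, gave 2585 genes and 15 lists and ended the calls of Timp1 (adjusted p = 0.053), Rplp0 (adjusted p = 0.060) and Cyp39a1 (adjusted p = 0.088) and gained that of Dnase1l3 (adjusted p = 0.0096). Same-numbered libraries showed no clear shared deviation (correlations of 0.15, 0.23 and -0.09), although so few libraries cannot exclude that the numbers pair the samples. The difference between groups in the share of the 10 most abundant genes, 7.14 percentage points, was 4.78 without celastrol replicate 1 and 11.02 without celastrol replicate 2, the ends of its range. RLE, upper-quartile and total count scaling, the 2 count models planned as other tests, voom and a mean of 50 counts need counts and were not run, and no mitochondrially encoded gene was there to leave out. An FPKM below 1 rests on few reads at this depth (18.9 to 19.8 reads for 1 FPKM over 1 kilobase), which limits Cyp7a1, Abcc4, Tnf and Il6.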

Other observations

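The gene families described first, and the tests of fasting, time of day and hepatocyte share, were chosen after the data were seen, whereas those of gene length, abundant transcripts and other splits of the libraries were set before.

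Families were formed from the letters that open a gene symbol, and 13 of 159 families with at least 8 tested members passed the camera test, none of them with an estimated correlation (adjusted p = 0.997). Subunits of the 26S proteasome regulatory particle named Psmd fell in 8 of 14 cases and rose in none (camera adjusted p = 0.039). Psmd8 fell from 102 to 57.4 FPKM (limma adjusted p = 0.0057) and Psmd11 from 53.5 to 31.9 FPKM (limma adjusted p = 0.0075). Under median-ratio scaling 6 fell and 1 rose. Unconventional myosins named Myo fell in 9 of 12 cases and rose in none (camera adjusted p = 0.039), with Myo1c from 19.6 to 6.52 FPKM (limma adjusted p = 0.00024), and in 4 of 12 after median-ratio scaling. Interferon-inducible genes named Ifi rose in 6 of 10 cases and fell in 1 (camera adjusted p = 0.00047). Ifi27l2a rose from 1.80 to 7.61 FPKM (limma adjusted p = 0.0076) while its neighbour in name Ifi27l2b fell from 14.4 to 7.19 FPKM (limma adjusted p = 0.019). The Ifi27l2b call was lost under median-ratio scaling, where 6 Ifi genes rose and none fell, with the 20 most abundant genes left out, after quantile normalization, and without ANIT replicate 1 or 3 or celastrol replicate 3 (adjusted p from 0.058 to 0.091).

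Albumin mRNA, among the most abundant liver transcripts, fell from 32513 ± 5321 to 6985 ± 2658 FPKM (SD, n = 3 each, Alb log2 fold change -2.27, limma adjusted p = 0.0024), while Saa1 rose from 8689 ± 3393 to 27438 ± 10734 FPKM (limma adjusted p = 0.025). The Saa1 call was lost after quantile normalization and without ANIT replicate 2 or 3 or celastrol replicate 1 or 3 (adjusted p from 0.056 to 0.088). Prtn3 stood at 42.97, 33.15 and 30.16 FPKM with celastrol, where Elane, a granule protease gene beside it on the chromosome, stood at 1.4, 0.23 and 1.63 FPKM and Mpo at 0.63, 0.24 and 2.96 FPKM. With ANIT, Prtn3 stood at 2.94, 3.75 and 4.77 FPKM and Elane at 0.06 FPKM in each library. Mpo stood at 0.08 and 0.04 FPKM in ANIT replicates 1 and 3 and was not listed in replicate 2. Elane and Mpo were thus also higher with celastrol, but lay below the filter and did not pass without it (limma adjusted p of 0.086 and 0.21). Celastrol replicate 2 differed from replicates 1 and 3 in Car3 (146.88 against 2.31 and 1.26 FPKM) and Hsd3b5 (33.06 against 4.23 and 2.81 FPKM). ANIT replicate 1 had 109.31 FPKM of Mup7, against 1137.97 and 4107.62 FPKM in ANIT replicates 2 and 3.

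The real grouping gave 2652 genes and the highest of the other 9 splits of the 6 libraries into 3 and 3 gave 3. Only 1 of the 10 splits gave as many as the real one, and 10 splits are too few for a share under 0.05.

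More genes were lower than higher with celastrol (2185 against 467). A difference in gene length argues poorly for this, since the median log2 fold change was below 0 in each of 10 length classes, the highest being -0.14. Abundant acute phase transcripts taking reads from all others stay open as a part of it. With the 20 most abundant genes left out, 61.7% of calls were lower, between the bounds set in advance (60% or less if they were the cause, 75% or more if not), and the median of all genes moved from -0.17 to -0.03. The median difference from the ANIT mean was -0.07 in celastrol replicate 2, where those 20 genes took the smallest share of reads of the celastrol libraries, and -0.21 and -0.24 in replicates 1 and 3.

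Cholesterol synthesis genes fell in 22 of 25 cases and lipogenesis genes in 11 of 21, and neither list passed with an estimated correlation (adjusted p of 0.50 and 0.75), nor did lipogenesis without ANIT replicate 2 (adjusted p = 0.062) or among genes at a mean of 5 FPKM or more (adjusted p = 0.11). Fasting of that group before collection lowers such genes in liver, but of 15 fasting-induced genes 5 fell and none rose, with a median log2 fold change of -0.83 (-0.65 after median-ratio scaling) and a highest value of 0.43, which argues against it, although G6pc, also raised by fasting, was higher. Time of day at collection cannot be told apart from treatment. The mean log2(FPKM + 1) of cholesterol synthesis genes differed by 1.15 between the lowest ANIT and the highest celastrol library, more than the range within a group. The contrast of clock genes ran from -1.24 to 2.58 with celastrol and from 1.16 to 2.86 with ANIT, so the celastrol libraries lay within or below the ANIT range. Celastrol replicate 2, with a clock contrast of 2.58, had the lowest cholesterol synthesis mean (4.67) but the highest lipogenesis mean (4.58) of the celastrol libraries. Celastrol replicate 3, with a contrast of -1.24, had the highest cholesterol synthesis mean of that group (5.63) and a lipogenesis mean of 4.25. The cholesterol order runs against time of day and the lipogenesis mean of replicate 2 with it, so single libraries cannot decide. An effect of celastrol itself stays open and was not tested further.

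Macrophage, endothelial and neutrophil markers lay above other genes at the preset correlation of camera and did not pass with an estimated one (adjusted p of 0.50, 0.64 and 0.44), and their mean log2(FPKM + 1) per library overlapped between groups for macrophage markers (2.86, 3.54 and 3.87 with ANIT, 3.93, 3.87 and 3.71 with celastrol) and endothelial markers (2.30, 2.71 and 2.13 with ANIT, 2.71, 3.12 and 2.40 with celastrol) but not for neutrophil markers (1.56, 2.05 and 1.84 with ANIT, 2.38, 2.41 and 2.59 with celastrol). A lower share of hepatocytes in the tissue would raise the markers of all other cell types alike, whereas the median log2 fold change was 0.48 for the 51 tested markers of those 3 kinds and -0.04 for the 21 tested cholangiocyte and stellate markers (permutation p = 0.00039, 100000 resamples, two-sided, genes not being independent replicates), a difference of -0.52 that was -0.31 without ANIT replicate 1 (permutation p = 0.072, 10000 resamples), and stellate markers passed the list test above other genes without celastrol replicate 3 (adjusted p = 0.0014). Erythroid and adipocyte markers had medians of -1.48 over 7 and -0.74 over 6 tested genes, the opposite way to such a loss. Past the threshold, 1 erythroid marker rose and none fell, and 3 adipocyte markers fell and none rose. In celastrol replicate 2 the mean log2(FPKM + 1) of both lists (4.31 and 3.02) lay within the ANIT ranges (4.21 to 4.71 and 2.56 to 3.06). With both lists added the difference passed in all 6 fits that leave out 1 library (permutation p = 0.0001 in each, the smallest that 10000 resamples can give). These values show that the markers did not move alike, but they cannot decide on a loss of hepatocytes. Neither the erythroid nor the adipocyte list passed (camera adjusted p of 0.84 and 0.15), and the adipocyte gene Adipoq was listed in only 1 library. The permutation shuffled genes and not libraries, and bile duct cells are themselves the target of ANIT. The mean of the 3 kinds minus that of the other 4 lists separated the groups by 0.27. That is less than the ranges within them (0.60 with ANIT and 0.66 with celastrol). A lower hepatocyte share therefore stays open, as does a change in the number or state of the cells whose markers rose, with celastrol as a candidate cause.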
